A study of Danio rerio with 8 samples.

How the data were processed

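Total RNA from 8 pools of embryos was labelled with Cy3 or Cy5 and hybridised to 4 Agilent two-colour arrays, per the labels' protocols. The series text describes the samples as biological duplicates. The deposited table holds linear intensities, which the authors extracted with Agilent Feature Extraction, per the submitters' processing notes, and quantile normalised after splitting the channels in Genedata Analyst, per the series text. All 8 columns hold the same sorted values, with a median of 119 and a range from 5.21 to 620468, so any difference in total RNA or overall signal was removed before deposit. The background correction is not given in the sources used here. Of 43663 rows, 60 control probes were left out of the tests.

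Intensities were log2 transformed with a floor of 1, which changed 0 values. Groups came from the sample titles, and dye and array from the labels. The main model was fitted with limma 3.58.1 in R 4.3.3 to all 8 samples, with 4 group means and a dye term, the array as a random block with an estimated correlation of 0.611, and moderated tests with 3 residual and 1.71 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over 43603 probes and a threshold of 0.05. Klf2b against control and the combined injection against Klf2a lie within arrays. The other comparisons cross arrays, and a difference shared by Klf2a and the combined injection against the other groups cannot be separated from the array set. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

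The tests, the alternatives and the rule for named probes were fixed before the data were examined. The rule took, per direction, the probes past the threshold with the largest fold whose samples lay on the same side of both samples of the other group, and filled short lists by the smallest unadjusted p. It was written for gene symbols, with always klf2a, klf2b and klf17, and up to 10 per direction against control and 5 otherwise. As the files do not pair probes with names, it was applied to probe identifiers, at most 2 per direction and comparison. The klf transcripts and the gene list tests were not run. Background was taken as 2 times the intensity of the negative control probe in each sample, a level chosen after the data were seen. A probe below it in a sample is called not well above background, and folds against such groups use that level as a lower bound.

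Further counts were added after the data were seen. Concordant probes are at least 2-fold apart the same way in both pairs of samples. Pairs were formed within dyes, or, for the comparisons within arrays, on each array after subtracting the dye difference of the other arrays. That difference enters both of these pairs with opposite signs, so they are not independent and lean towards discordant counts. They were counted over all probes and over the brighter ones, and the brighter ones were used for shared and group-specific counts after both sets of counts had been seen. The spike-in level is the mean deviation of 10 E1A spike-in probes from their dye mean, and it entered as a covariate or as a shift. Spike-in Cy5 over Cy3 ratios correlated between arrays at r of 0.990 or more, a check of the dye labels. Simulated unchanged data used the same pairs with the fitted spread and array correlation, with 20 simulations, and were repeated with the calibrated correlation given below. Their noise was drawn independently for each probe, so they hold no axis shared across probes. Values above the simulated ones therefore need not come from the morpholinos.

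The fit was tested on simulated data with 50 of the brighter probes changed at each of 4 sizes in both the Klf2a and Klf2b groups, among 43603 probes, made with an array correlation of 0.611. The estimated correlation was 0.739, above the value put in. For Klf2a against control, the shares recovered were 0%, 26%, 96% and 98% at 1, 2, 4 and 6 log2, with 0 false calls. For Klf2b against control, they were 38%, 94%, 100% and 100%, with 13 false calls and 8.02% of unchanged probes at an unadjusted p under 0.05. For the combined injection against Klf2a, they were 36%, 98%, 100% and 100%, with 11 false calls and 7.67%. With the correlation set to the simulated value, the last 2 comparisons gave 5 and 6 false calls, and 5.04% and 4.99%. With the estimated correlation, within-array p-values are therefore too small. A correlation of 0.402 is the input at which simulated data, over 8000 probes, return the 0.611 estimated here, and it was used as an added alternative. For the brighter probes alone the estimate was 0.683 and the calibrated value 0.500. Where a fit left too few degrees of freedom to estimate the correlation (replicate block, spike-in covariate, samples left out), 0.611 was used.

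Groups of 2 are too small for tests of outlying samples or other splits. Alternatives covered the dye term, the array block, the samples in the fit, the normalisation, filters on dim probes, the variance prior, a pseudocount of 16 and each sample left out in turn. The fit to the compared samples alone also had no dye term and no array block.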

Results

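Whole wild-type zebrafish embryos at 4.7 hours post fertilisation were profiled after injection of morpholinos, antisense oligomers that block the translation or splicing of a target transcript. The targets were Klf2a and Klf2b, zinc finger transcription factors of the Krüppel-like family. The 4 groups received 4 ng of a standard control morpholino, 4 ng of Klf2a morpholino, 4 ng of Klf2b morpholino, or 2 ng of each Klf2 morpholino together, called the combined injection here. Each group held 2 samples of 60 to 100 pooled embryos, 1 labelled with Cy3 and 1 with Cy5. The 8 samples were the 8 channels of 4 arrays. Klf2a and the combined injection shared 2 arrays, and Klf2b and the control shared the other 2. Values were probe intensities for 43603 probes, and the number of arrays limits their precision. The files used here do not pair the probes with gene names, so probes are given by identifier, and the levels of the targeted transcripts were not analysed here.

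Replicates correlated across all probes at r = 0.970 for the control, 0.974 for Klf2a, 0.979 for Klf2b and 0.971 for the combined injection. Probes are not independent replicates. The first principal component of the brighter probes, 21801 probes above the median mean intensity, held 47.4% of the variance after dye centring. Its scores were -57.2 and -43.1 for the Klf2a samples, -12.3 and 22.3 for Klf2b, 19.1 and 11.3 for the combined injection, and 1.72 and 58.2 for the control. The level of 10 spike-in probes, RNA of known amount added to each labelling, ran with these scores. Its deviation from the dye mean was -0.49 ± 0.06 log2 for Klf2a, -0.001 ± 0.38 for Klf2b, 0.21 ± 0.10 for the combined injection and 0.29 ± 0.35 for the control (SD, n = 2 each). Over the 8 samples the score and the spike-in level had r = 0.971 (exact permutation p = 0.000149, adjusted 0.000298) and rho = 0.929 (exact permutation p = 0.00223). The permutations treat the 8 samples as exchangeable, although they share arrays and groups. Without the 2 samples farthest from the median spike-in level, both Klf2a, r was 0.919. Over all probes the first component gave r = 0.854 (exact permutation p = 0.00531, adjusted 0.00531), rho = 0.833 (exact permutation p = 0.0154) and, without those samples, r = 0.674. These 2 relations were the family computed, and each pair of arrays held too few samples for a value of its own.

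**Figure D1:**
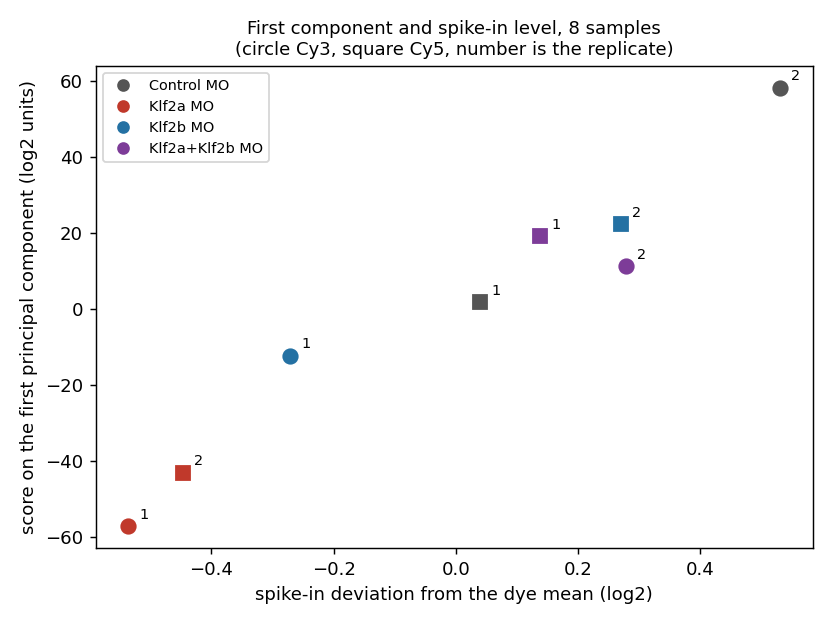
Score on the first principal component of the brighter probes (y axis, log2 units) against the spike-in deviation from the dye mean (x axis, log2) for each of the 8 samples, coloured by group, with circles for Cy3, squares for Cy5 and the replicate number beside each point. The 2 Klf2a samples sit lowest on both axes, at -57.2 and -43.1, and control replicate 2 sits highest, at 58.2.

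The effect of Klf2a morpholino was read against the control morpholino, across arrays. A single probe passed the threshold, A_15_P260956, which rose at least 24.9-fold. It measured 9.06 ± 0.03 log2 in Klf2a embryos and 2.73 ± 0.12 in controls (SD, n = 2 each), where both samples were not well above background. The limma estimate was 6.33 log2 (SE 0.17, adjusted p = 0.0214), and both Klf2a samples lay above both controls. It was 4.601 with a pseudocount of 16, which understates the change of dim probes, and 7.11 (SE 0.39) after a shift to equal spike-in levels, and called with both. A_15_P356910, the next probe upward, measured 10.3 ± 0.04 log2 against 6.01 ± 0.41 (adjusted p = 0.289, limma), a difference of 4.28 that was 5.06 after that shift and 3.37 with the spike-in level as a covariate, and was also bright in the combined injection, at 10.1 ± 0.17. No probe passed downward. Unadjusted p under 0.05 was reached by 6788 probes, or 15.6%. With samples paired within dyes, 1366 probes were at least 2-fold apart the same way in both pairs, 740 higher and 626 lower, and 506 in opposite ways. The spike-in shift gave 4686 higher and 92 lower. Among the brighter probes these counts were 417, of which 264 were higher and 153 lower, and 16, against a mean of 35.9 the same way in simulated unchanged data, or 34.4 with a calibrated array correlation. The pair holding control replicate 2 had 4343 brighter probes at least 2-fold apart and the other pair 888. With limma, A_15_P260956 was not called with the spike-in level as a covariate (6.41 log2, SE 0.43), with a trended and robust prior (6.33, SE 0.37), from the compared samples alone (6.33, SE 0.19) or without any 1 of the 4 samples (6.23 to 6.44, SE 0.18 to 0.21). The SEs were larger and, except with that prior, fewer degrees of freedom were left, and 948, 7827, 4213 and 3920 to 11824 probes had an unadjusted p under 0.05.

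Klf2b morpholino was compared with the control on shared arrays with the dyes swapped. No probe passed the limma threshold, and the smallest adjusted p was 0.138, while 7277 probes had an unadjusted p under 0.05. A_15_P143451 measured 7.65 ± 0.19 log2 in Klf2b embryos and 5.07 ± 0.16 in controls, a difference of 2.59 (SE 0.15, adjusted p = 0.138, limma). It was called when the lower-intensity probes were left out (adjusted p = 0.00487, or 0.00738 with a calibrated array correlation, limma). The same probe measured 7.85 ± 0.14 in Klf2a embryos and 7.89 ± 0.05 in the combined injection. A_15_P171501 measured 5.25 ± 0.26 in controls and 3.10 ± 0.65 in Klf2b embryos, where both samples were not well above background (adjusted p = 0.138, limma). It was at least 1.92-fold lower in Klf2b, and the fitted difference of -2.15 was -1.12 with the pseudocount. The levels of A_15_P171501 were 3.19 ± 0.22 and 3.30 ± 0.74 in Klf2a and the combined injection, also not well above background. Concordant probes numbered 501, 320 higher and 181 lower (791 and 63 after the spike-in shift), and discordant ones 1501 over all probes. Among the brighter probes 86 were concordant, 73 of them higher, and 46 discordant, against 5.25 concordant in simulated unchanged data, or 9.15 concordant and 57.6 discordant with a calibrated array correlation. With the lower-intensity probes left out, limma called 1364 (876 higher and 488 lower) with the estimated array correlation and 92 (77 and 15) with a calibrated one. Over all probes, where limma called none, the 7277 with an unadjusted p under 0.05 were 4600 with the calibrated correlation, 4047 with the array as a fixed block, 2668 without the dye term, 1862 without the array block and 1746 from the compared samples alone. Limma called 2 with the trended and robust prior, and 2587 after the spike-in shift, 2356 higher and 231 lower.

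Against the control, the combined injection crossed arrays and gave no called probe with limma, with 4105 at an unadjusted p under 0.05. Its smallest adjusted p, 0.0600, was that of A_15_P260956, at 7.81 ± 0.04 log2 and at least 10.5-fold above the control, a difference of 5.08 that was 3.41 with the pseudocount and then called. A_15_P545502 measured 10.2 ± 0.19 against 5.49 ± 0.31 (adjusted p = 0.0901). A_15_P103961 measured 8.96 ± 0.28 against 12.7 ± 0.07 (adjusted p = 0.121), and A_15_P193306 measured 8.17 ± 0.11 against 10.7 ± 0.16 (adjusted p = 0.266). Both were called when the lower-intensity probes were left out (adjusted p = 0.00523 and 0.0135, limma). A_15_P103961 was also called with the trended and robust prior (adjusted p = 0.0139, limma). Concordant probes numbered 1256, 552 higher and 704 lower, and discordant ones 773. Among the brighter probes the balance was reversed, with 177 higher and 123 lower of 300 concordant, and 26 were discordant, against 37.0 concordant in simulated unchanged data, or 31.2 with the calibrated correlation. When the lower-intensity probes were left out limma called 22, 9 higher and 13 lower, or 47 with a calibrated correlation, and under the other settings from 0 to 2.

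Whether the combined injection differed from Klf2a morpholino was tested on shared arrays with the dyes swapped. A_15_P545502 rose 44.4-fold, from 4.75 ± 0.07 to 10.2 ± 0.19 log2 (SE of the difference 0.12, adjusted p = 0.010, limma). A_15_P195966 rose 9.01-fold, from 5.26 ± 0.67 to 8.43 ± 0.33 (adjusted p = 0.0299). A_15_P103961 was 14.4-fold lower, 8.96 ± 0.28 against 12.8 ± 0.22 (adjusted p = 0.0171), and A_15_P193306 was 6.31-fold lower, 8.17 ± 0.11 against 10.8 ± 0.33 (adjusted p = 0.0299). Each of these 4 differences had the same sign on both arrays, and the smallest on any array was 2.35 log2 in size. After the spike-in shift, which moved the median of all probes to -0.695 log2, the 4 differences were 4.77, 2.47, -4.55 and -3.36, where they were 5.47, 3.17, -3.85 and -2.66 before, and that of A_15_P545502 was 4.82 with the pseudocount. Unadjusted p under 0.05 was reached by 13746 probes, or 31.5%. Concordant probes numbered 1085, 423 higher and 662 lower (26 and 5874 after the spike-in shift), and discordant ones 1446. Among the brighter probes 281 were concordant, 123 higher and 158 lower, and 56 discordant, against 5.55 concordant in simulated unchanged data, or 9.10 concordant and 58.8 discordant with the calibrated correlation. With limma the number of calls was 4937 without the dimmest probes, 9337 for the brighter probes (6323 with a calibrated correlation), 5499 with the trended and robust prior and 27858 after the spike-in shift, 530 higher and 27328 lower. It was 1 without the dye term, and 0 with the array as a fixed block (8650 at an unadjusted p under 0.05), without the array block (4788), from the compared samples alone (5377) and with the spike-in covariate (1164). The 4 differences, with SEs of 0.10 to 0.12, were the same with the fixed block (SE 0.15 to 0.18) and from the compared samples alone (SE 0.185 to 0.427). The last of these fits also had no dye term and no array block. Without the dye term, all samples gave SEs of 0.208 to 0.48. With the covariate the 4 differences were 5.50, 3.10, -3.81 and -2.47 (SE 0.34 to 0.42). Without any 1 of the 4 samples, where calls are given below, they were 5.281 to 5.666, 3.018 to 3.325, -3.991 to -3.708 and -2.718 to -2.596. In simulated data the array correlation was overestimated and 7.67% of unchanged probes reached an unadjusted p under 0.05 in this comparison, and with a correlation calibrated for this 2 of the 4 probes were called, A_15_P545502 and A_15_P103961.

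**Figure D2:**
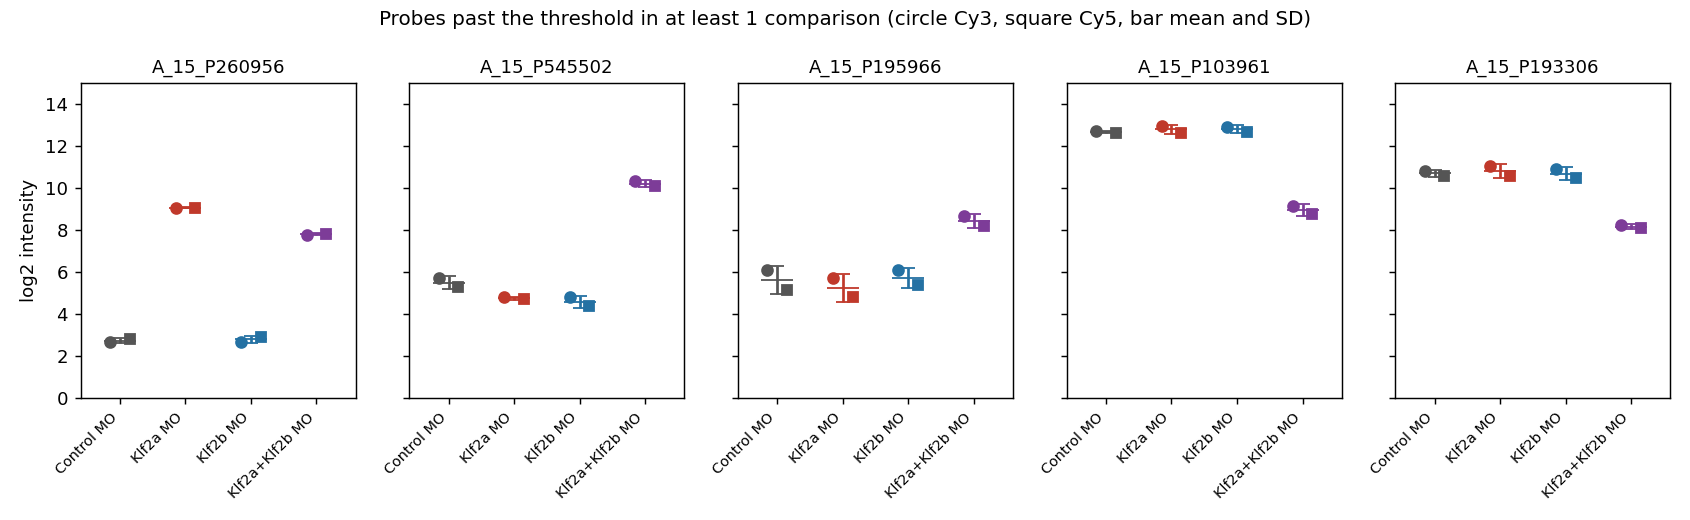
Log2 intensity (y axis) of the 5 probes past the threshold in at least 1 comparison, by group (x axis), with circles for Cy3, squares for Cy5 and bars for the mean and SD of 2 samples. A_15_P260956 is bright in both groups given Klf2a morpholino, at 9.06 and 7.81, and the other 4 probes differ in the combined injection.

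The combined injection was also compared with Klf2b morpholino, across arrays. A_15_P545502 rose at least 46.1-fold above 4.58 ± 0.29 log2, with 1 of the 2 Klf2b samples not well above background, and A_15_P260956 rose at least 11.4-fold above 2.78 ± 0.16, with both not well above background (adjusted p = 0.0397 for each, limma). With the pseudocount the differences were 4.92 and 3.39. No probe passed downward, and 3174 had an unadjusted p under 0.05. Between the single injections, A_15_P260956 was at least 27.0-fold lower in Klf2b than in Klf2a embryos (-6.27 log2, SE 0.17, adjusted p = 0.0224, limma, and -4.58 log2 with the pseudocount), with 3785 probes at an unadjusted p under 0.05. Among the brighter probes, 174 were concordant and 15 discordant for the combined injection against Klf2b, and 306 and 13 for Klf2b against Klf2a. The simulated concordant counts were 38.2 and 36.0, or 29.8 and 31.9 with the calibrated correlation. With limma, no call was left with the spike-in covariate, where the SEs were larger, with 2063 and 1064 probes at an unadjusted p under 0.05. In the first of these comparisons A_15_P545502 was 5.64 log2 (SE 0.20) before and 5.65 (SE 0.26) with it, and A_15_P260956 5.03 (SE 0.17) and 5.01 (SE 0.23). In the other, A_15_P260956 was -6.32 (SE 0.31) with it. No call was left from the compared samples alone either (3239 and 4168 at an unadjusted p under 0.05), or without any 1 of the 4 samples (2509 to 4491 and 2419 to 4930), where these differences were 5.48 to 5.80, 4.92 to 5.14 and -6.39 to -6.16. After the spike-in shift the first comparison had no call, with 1551 and differences of 5.43 (SE 0.43) and 4.82 (SE 0.39), and with the trended and robust prior A_15_P260956 was called in neither (SE 0.37).

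Each morpholino was at 2 ng in the combined injection and 4 ng alone. Effects additive on the log2 scale and in proportion to dose would place the combined injection at the mean log2 value of the single ones. Against that mean, A_15_P545502 was at least 45.3-fold higher, with 1 of the 4 single-injection samples not well above background (adjusted p = 0.0128, limma), and A_15_P195966 7.64-fold higher (adjusted p = 0.0497). The first difference was 4.87 log2 with the pseudocount and 5.56 without. A_15_P103961 was 14.5-fold lower (adjusted p = 0.0232) and A_15_P193306 6.04-fold lower (adjusted p = 0.0497). At an unadjusted p under 0.05 there were 8149 probes. In the single injections these 4 probes differed from the control by -0.91 to 0.14 log2, with adjusted p from 0.152 to 1.00 (limma). With the calibrated array correlation 2 of the 4 were called. With limma none was called with the spike-in covariate, with 1473 probes at an unadjusted p under 0.05, as the SEs, 0.11 to 0.13 before, were 0.24 to 0.30. In the order given, the differences were 5.57, 2.89, -3.83 and -2.47 log2 with it and 5.56, 2.93, -3.85 and -2.59 before. None was called from the compared samples alone (4965), 1 without the array block and 2 without the dye term, with the differences unchanged. Without any 1 of the 6 samples, where calls are given below, the differences were 5.422 to 5.695, 2.78 to 3.088, -3.995 to -3.713 and -2.656 to -2.534.

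**Figure D3:**
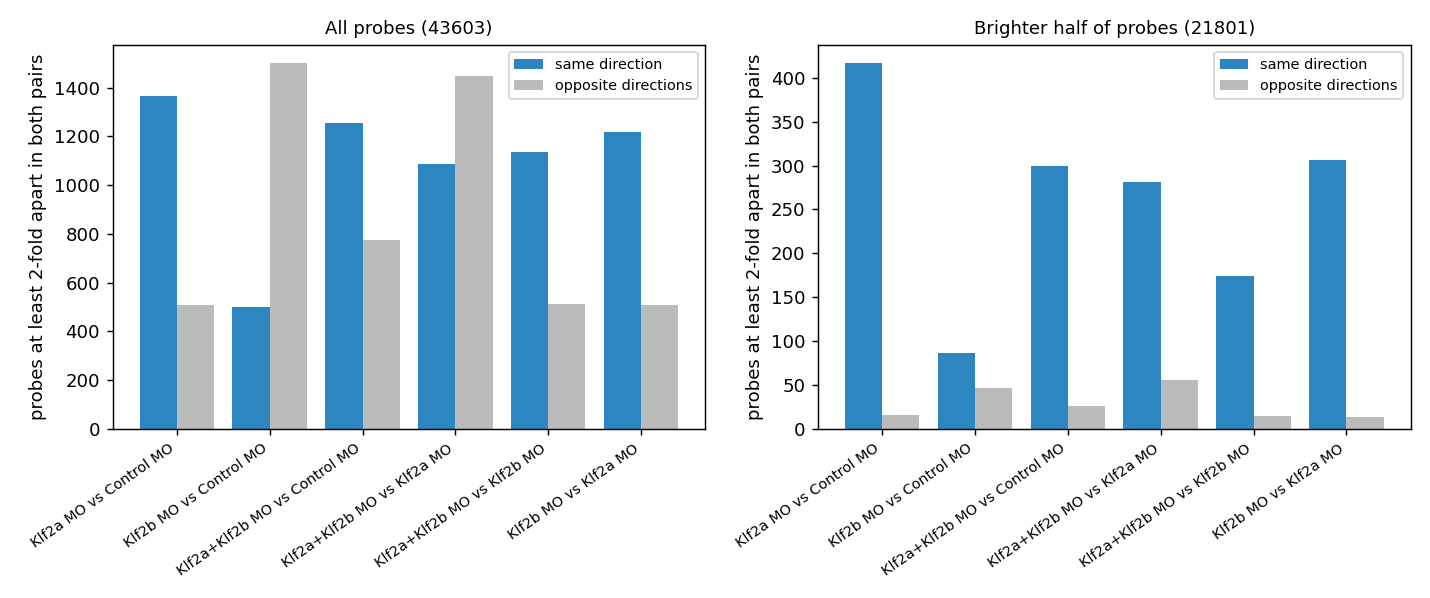
Number of probes (y axis) at least 2-fold apart in both pairs of samples, in the same direction (blue) or in opposite directions (grey), for 6 comparisons (x axis), over all 43603 probes (left) and the 21801 brighter probes (right). For Klf2a against control the counts are 1366 and 506 on the left and 417 and 16 on the right, and for Klf2b against control 501 and 1501 on the left and 86 and 46 on the right.

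The comparisons against the control share its 2 samples. Log2 fold changes correlated across probes at r = 0.502 for Klf2a and Klf2b, where simulated unchanged groups gave 0.312, at 0.588 for Klf2a and the combined injection, against 0.805, and at 0.425 for Klf2b and the combined injection, against 0.311. The covariances exceeded the simulated ones by 0.120, 0.0802 and 0.0816, or by 0.104, 0.114 and 0.0654 with the calibrated array correlation. With no array block the excess was 0.0534, 0.139 and 0.0152, and the simulated r of the first and last pair was 0.499 and 0.498. Of the brighter concordant probes, Klf2a and Klf2b shared 24 (21 higher and 3 lower), where unchanged groups gave 1.1 (2.2 with the calibrated correlation) and independent lists 0.884 and 0.0912. Klf2a and the combined injection shared 72 (53 and 19), against 12.05 (8.75), and 2.14 and 0.863. Klf2b and the combined injection shared 42 (37 and 5), against 1 (1.9), and 0.593 and 0.0734. A split of the controls would leave 1 for each comparison and was not made, so part of the excess may come from the shared controls. Without control replicate 1 the excess covariances were 0.432, 0.386 and 0.301, and without control replicate 2 they were 0.0935, 0.129 and 0.148.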

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

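The tests below were chosen after the results were seen, except the 3 on the amount of labelled RNA, which were set before their results but after the spike-in levels were seen; the one on separate arrays was added after the first of them.

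A_15_P260956 differed between the Klf2 morpholinos, at -6.27 log2 for Klf2b minus Klf2a and 5.03 for the combined injection minus Klf2b, both past the threshold with limma, and as Klf2b was not well above background the bounds on their sizes are 4.75 and 3.51. Both groups given Klf2a morpholino share arrays, and a mark of equal brightness in both channels is argued against, as the channels differed by -1.25 log2 (SE 0.10, unadjusted p = 0.000106, adjusted p = 0.0693, limma), at -1.20 and -1.29 on the arrays. The sign was kept with the dyes swapped, so the difference followed the sample and not the channel. A mark of unequal brightness was not tested and stays possible. The control probe RC2, described below, was bright on the second array, and its channels differed by 0.74 log2. The ratio of Klf2a to the combined injection was 2.38 (95% interval 1.97 to 2.87). The interval rests on the estimated array correlation and is likely too narrow. On the linear scale, unlike the comparison with the mean of the single injections, the ratio may follow the dose of Klf2a morpholino, whose ratio is 2. A_15_P356910, bright in the same groups, had a ratio of 1.15, which does not follow that dose. A difference in embryos or handling between the array sets was not tested and stays open.

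The combined injection differed from Klf2a at 4 probes, by 5.47 log2 for A_15_P545502, 3.17 for A_15_P195966, -3.85 for A_15_P103961 and -2.66 for A_15_P193306, and from Klf2b at A_15_P545502 by 5.64. Dye bias would change sign with the dyes, but every difference kept its sign on both arrays and the smallest was 2.35 in size. This outcome was largely set in advance, as the balanced dye swap and the dye term keep such bias out of the called probes. With the spike-in level as a covariate the differences were 5.50, 3.10, -3.81 and -2.47, the smallest 2.47 in size. This outcome was also largely set in advance. The slope of the covariate rests on differences between replicates, which are small at probes called for a small SE. The covariate therefore cannot decide whether the amount of labelled RNA is the cause. After the spike-in shift the differences were 4.77, 2.47, -4.55 and -3.36. The shift cannot decide on the amount of labelled RNA either, as it moves every probe alike, by the 0.70 log2 between the groups in spike-in level. No call was left with the covariate (adjusted p = 1 for each, limma, where all settings ranged from 7.67e-05 to 1), since the SEs, 0.10 to 0.12 before, were 0.34 to 0.42. With the calibrated array correlation A_15_P545502 and A_15_P103961 were called and the other 2 were not (adjusted p = 0.0166, 0.0316, 0.0756 and 0.0756, limma), with the differences unchanged, and an effect of the combined injection stays open.

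The Klf2a samples stood apart on the first component, at -57.2 and -43.1, but the axis also appeared without any difference in morpholino. Klf2b replicate 2 minus replicate 1, 0.54 apart in spike-in level, was taken after removing the mean dye difference of all 8 samples. Across brighter probes it correlated at r = 0.526 with control minus Klf2a, whose control samples share its arrays. With the combined injection minus Klf2a, 0.70 apart and on other arrays, r was 0.518. The samples of these groups enter the removed dye difference, so the correlated values are not independent. Both correlations may follow the amount of labelled RNA. Control replicates, 0.49 apart, gave 0.693 against the combined injection minus Klf2a but lie on the Klf2b arrays and are not separate support. Replicates of the combined injection and of Klf2a, 0.14 and 0.09 apart, gave -0.172 and 0.149 against control minus Klf2a. The array set is argued against by the combined injection, which lay at least 54.4 from Klf2a on the same array, where Klf2a replicates differed by 14.1. Scores predicted from the spike-in level of the other 6 samples left residuals of -16.9 and -10.1 for Klf2a, where the other 6 ranged from -14.6 to 11.7, so an added effect of Klf2a morpholino cannot be told apart with 2 samples. The spike-in level does not separate the amount of RNA labelled from the share of messenger RNA in it, which was not tested.

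A control probe left out of the comparisons, RC2, was bright in both channels of the second array, at 9.70 log2 for Klf2a replicate 2 and 8.96 for replicate 2 of the combined injection, against 3.27 and 3.91 in the control samples.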

How the results depend on the processing

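The calibrated correlations, both spike-in settings, the crossed pairing and the concordant counts were chosen after the data were seen, and the other alternatives were planned. Named probes kept their direction in 514 of 514 alternative values, but calls did not hold: 119 were lost and 28 gained. The directions are no test of stability. Several settings cannot change the fitted difference in this balanced design, and the probes were chosen from these same data. Repeated quantile normalisation, median centring and cyclic loess moved no count of calls by over 1.5 times. Quantile normalisation and median centring can change little here, as the deposited columns already hold the same sorted values. Unless a construction is named, the cause was not tested. The replicate block, the spike-in covariate and the compared pairs of groups alone left 2 residual degrees of freedom, where the main model left 3, and the fixed array block left 1. Fits to the compared samples alone also had no dye term and no array block, so their lost calls need not come from the smaller set of samples. Dim probes limit the rest: signal was above background at 64.8% to 73.6% of probes per sample.

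With limma, calls for Klf2a against control, 1 with the main model, were 0 with the replicate block, the compared samples alone, the trend and robust prior and the spike-in covariate, and 7 without the lower-intensity probes (9 with their correlation calibrated), which left out A_15_P260956. For Klf2b against control, 0 with the main model, they were 1364 without those probes (92 calibrated), 2 with the trend and robust prior and 2587 after the spike-in shift (2356 higher and 231 lower). For the combined injection against control, 0 with the main model, they were 1 with no dye term, no array block, the trend and robust prior or the calibrated correlation, 2 without the dimmest probes or with a pseudocount of 16, and 22 without the lower-intensity probes (47 calibrated). For the combined injection against Klf2a, 4 (2 higher and 2 lower) with the main model, they were 1 with no dye term, 2 with the calibrated correlation, 0 with no array block, the replicate block, the fixed array block, the compared samples alone or the spike-in covariate, 4937 without the dimmest probes, 9337 without the lower-intensity probes (6323 calibrated), with 2 of the 4 among them as A_15_P545502 and A_15_P195966 were left out, 5499 with the trend and robust prior, and 27858 after the spike-in shift (530 higher and 27328 lower). For the combined injection against Klf2b, 2 with the main model, they were 0 with the replicate block, the compared samples alone and both spike-in settings, and 8 without the lower-intensity probes (9 calibrated), which left out both, while the trend and robust prior gave 2, of which 1 was shared with the main model. For Klf2b against Klf2a, 1 with the main model, they were 0 with the replicate block, the compared samples alone, the trend and robust prior and the spike-in covariate. Without the lower-intensity probes the single call was another probe, since A_15_P260956 was left out. For the combined injection against the mean of the single ones, 4 with the main model, they were 2 with no dye term or the calibrated correlation, 1 with no array block, 0 with the replicate block, the compared samples alone and the spike-in covariate, 206 without the lower-intensity probes (71 calibrated), again with 2 of the 4, 9 with the trend and robust prior and 47 after the spike-in shift (4 higher and 43 lower). At an unadjusted p under 0.05, these counts of 0 had 948 to 11829 probes. Same-numbered samples deviated together from their group means at r = 0.363 for control and Klf2b and 0.230 for Klf2a and the combined injection, which share arrays, and from -0.278 to 0.180 otherwise. With the dye difference removed the values were 0.752 and 0.652, and from -0.253 to 0.295 otherwise. That difference was estimated from the same samples, which by itself builds correlation into these values, so they do not measure pairing on their own. The numbers were not taken to pair samples beyond the arrays. The replicate block gave 0 calls in every comparison, and the crossed pairing of Klf2b and the combined injection as a block gave 0, with 3612 at an unadjusted p under 0.05.

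Leaving out each sample in turn gave from 0 to 0 calls in all 7 comparisons (2419 to 11824 at an unadjusted p under 0.05), with a lone sample assumed to vary like the other groups. The excess covariance ranged from 0.0935 to 0.432 for Klf2a and Klf2b, 0.129 to 0.386 for Klf2a and the combined injection, and 0.148 to 0.301 for Klf2b and the combined injection, when either control was left out. With no array block it was 0.0534, 0.139 and 0.0152.

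Concordant counts, in the order Klf2a, Klf2b and the combined injection against control, the combined injection against Klf2a and against Klf2b, and Klf2b against Klf2a, were 417, 86, 300, 281, 174 and 306 without the lower-intensity probes and 544, 122, 474, 400, 349 and 460 with the pseudocount. The spike-in shift left a median over all probes of 0.79 log2 for Klf2a against control, the largest of the comparisons, where it was 0.0126 before. It gave 4778 for Klf2a against control (98.1% higher, 54.2% before), 854 for Klf2b against control (92.6%, 63.9% before), 5900 for the combined injection against Klf2a (0.4%, 39.0% before) and 2279 for Klf2b against Klf2a (7.1%, 50.9% before). For the combined injection against Klf2b the shift left 14.4% higher, where it was 30.9% before. The klf transcripts and the gene list tests were not run.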

Other observations

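Among the 21801 brighter probes, all chosen after the data were seen, those with every sample of a group at least 2-fold beyond every sample of the other groups were counted after dye centring. The combined injection stood apart at 24 probes, 3 higher and 21 lower, the control at 16, 3 higher and 13 lower, Klf2a at 14, 6 higher and 8 lower, and Klf2b at 1, which was higher. Means over 20 simulations of unchanged groups were 0.45, 0.75, 0.50 and 0.30, or 0.60, 0.75, 0.90 and 0.80 with the calibrated array correlation. The simulations hold no axis shared across probes, such as the first component, which ran with the spike-in level. Counts above the simulated ones therefore need not come from the morpholinos. Of the ways to part the groups 2 against 2, Klf2a with the combined injection stood apart at 14 probes, 9 higher and 5 lower, where the simulation gave 2.65, or 1.2 calibrated. Klf2a with Klf2b did so at 0 and Klf2b with the combined injection at 1, which was lower. The split with 14 also follows the arrays, so the array set and Klf2a morpholino are confounded in it. No test of the differences between these counts was run.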
